A study of Mus musculus with 6 samples.

How the data were processed

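Total RNA had been extracted from tumors with Trizol and made into libraries with an NEBNext Ultra kit, per the labels' protocols, for 3 model and 3 DMDD liposome samples. Groups and replicate numbers were taken from the sample descriptions. Those descriptions call the animals rats, while the organism field and the strain name a mouse; the gene symbols are those of mouse, and 16720 of 16763 matched a mouse gene name table. One deposited table covered all 6 samples, with 16763 genes by symbol, and every column of values matched a sample or a comparison.

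The table's unnormalized columns hold read counts per gene, per the file headers, and the values were whole numbers with a different total in each sample. Further columns hold a normalized signal, which the authors made by dividing each count by a size factor per sample, as shown by a constant ratio of the columns. The authors also deposited FPKM values, and these follow from the counts, the column totals and a whole-number gene length for all 16763 genes, within 0.01 of a base. The deposited log2 fold changes are model over DMDD liposome, the opposite of the direction used here: their sign was that of the ratio of the normalized group means for 12903 of 12924 genes. The deposited p-values and adjusted p-values come with DESeq2 named in the submitters' processing notes, without a version. A DESeq2 fit with default settings gave a p within 1% of the deposited p for 16705 of 16736 genes. Of the 2302 genes whose adjusted p was missing in that fit, 2265 were listed in the authors' deposited table with an adjusted p of 1. The submitters' processing notes name genome build mm9. The aligner, the counter, the gene annotation and any strand setting are not given in the sources used here, so the split of reads between near-identical genes (Lyz2 and Lyz1, or Ldha and its pseudogenes) and between overlapping genes is uncertain. The reference held here was of another build, so gene names only were used and no coordinates are given.

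The counts as deposited were tested in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr (minimum count 10, minimum total 15), leaving 12891 tested and 3872 not tested. Libraries were scaled by TMM, and the quasi-likelihood test (two-sided) compared DMDD liposome with model over all 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.0466. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. CPM were scaled by TMM and are given as mean ± SD over 3 libraries per group. Log2 CPM used a prior count of 2. Total counts ran from 13037500 to 15616840 per library, and a gene at 3 counts in a library is at 0.192 to 0.230 CPM, below which levels are dominated by counting error.

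Gene lists were fixed before the data were examined: 44 lists of pathways and cell types, with 718 genes, of which 587 were tested. camera in limma 3.58.1 compared each list of at least 5 tested members with all other genes, at a preset inter-gene correlation of 0.01, and adjusted over the 40 lists tested. Lists of erythroid markers, platelet and megakaryocyte markers, skin and hair follicle keratinocyte markers and luminal mammary and milk protein genes had fewer than 5 tested members and were not tested. The labels give the sex as male, which is unusual for a breast tumor model, and a list of 6 sex-linked genes kept for checking labels had 0 genes in the table, so the label was not checked with it. The series design speaks of several groups, of which 2 are held here. Genes were named by a rule fixed at the same time. Its first part took the 10 largest fold changes per direction among genes past the adjusted threshold, with a mean of at least 1 CPM, no overlap between the groups and no predicted genes, pseudogenes or receptor variable segments, and it named none. Its second part took the 3 members with the smallest adjusted p of each called list, ties broken by the unadjusted p. A final part took up to 2 members past the threshold in each uncalled list, and named none. The 10 genes per direction with the smallest p in the authors' deposited table were added after its values were seen. Some genes that these rules take are not reported here.

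Alternatives fixed at that time were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0's Wald test, a replicate block, a threshold of 0.01, limma-voom with sample quality weights, leaving out each library in turn and, for lists, an estimated correlation and fry. Alternatives for normalized values were not needed, since counts were deposited. DESeq2 without each library and edgeR with a robust prior were added after seeing the data.

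The tests were run on simulated counts for the 12891 genes of this comparison, drawn from the real means, dispersions and library sizes. Of 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 54% and 91%, with 4 false calls (2.68% of its calls). DESeq2 recovered 73% and 98%, with 41 false calls (19.3% of its calls). The changed genes had a mean of at least 1 CPM, and the simulated libraries differed in no pattern beyond the groups. Recovery in the real data may therefore be lower. DESeq2 was given only the filtered genes here, unlike its fit to the real counts. Among 40 simulated lists of 15 genes, camera called the 1 list lowered 2-fold and 0 unchanged lists. The simulated genes were drawn independently of each other, whereas the correlation estimated within the called real lists ran from 0.160 to 0.884. The 0 false calls therefore do not show how often camera at the preset correlation calls unchanged lists in these data.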

Results

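RNA was sequenced from breast tumors grown in BALB/c mice from 4T1 cells, a mammary carcinoma line of that strain. One group of tumors came from mice bearing such tumors without that treatment, called the model group, and the other from mice given DMDD carried in liposomes, which are lipid vesicles used to deliver compounds. DMDD is named in the labels only by its abbreviation. Each group had 3 libraries. The labels state that mice were allotted to groups at random but not which mouse gave which library, so p-values measure only the spread between these samples, which may be technical. The model libraries held 13037500, 15484929 and 15616840 counts for replicates 1 to 3, and the DMDD liposome libraries held 13756836, 13419951 and 14580202. Between 14953 and 15409 genes had at least 1 count in a library. At these depths 3 counts stood for 0.192 to 0.230 CPM, the usual measure of a count relative to its library's total, and values near that level carry a large counting error. Genes are identified by symbol, as in the deposited table.

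The comparison asked how the tumor transcriptome differed after DMDD liposome treatment. Cholesterol synthesis genes fell together in the DMDD liposome tumors, with a median log2 fold change of -0.86 (0.550-fold) over 20 members, all of them negative (adjusted p = 0.875 with an estimated correlation). Markers of mast cells and basophils fell with a median of -1.90 over 9 members, and epithelial tumor cell markers with a median of -0.58 over 14 (adjusted p = 0.875 with an estimated correlation for both). In all 3 lists model replicate 1 stood nearer the DMDD liposome libraries, with centred means of -0.32, -0.26 and -0.13 against DMDD liposome group means of -0.38, -0.89 and -0.28. Macrophage and monocyte markers rose, with a median of 0.47 over 18 members (adjusted p = 0.875 with an estimated correlation). In all, camera called 11 of the 40 lists tested, 5 higher and 6 lower, and with an inter-gene correlation estimated for each list none of the 11 calls held (adjusted p = 0.875 for each of them).

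Among single genes, edgeR's quasi-likelihood test called 0 of 12891 after Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.603. At an unadjusted p under 0.05 it found 986 genes, 559 higher and 427 lower, where chance would give 645. Setting model replicate 1 and DMDD liposome replicates 1 and 3 against the rest gave 1558. Such an excess is thus not particular to the treatment groups. The 3 values of each group did not overlap for 1660 of the tested genes (12.9%, against 10% by chance). DESeq2 on the same counts called 59 genes, 31 higher and 28 lower. Without model replicate 1, edgeR called 112 genes and DESeq2 called 867. Each gene named from the gene lists was therefore short of edgeR's threshold over all genes, and its values are given as measurements.

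The authors' deposited table, which lists its fold changes as model over DMDD liposome, called 58 genes at an adjusted p under 0.05, of which 31 were higher and 27 lower in DMDD liposome. The genes named from that table were chosen after its values were seen, from the 10 with its smallest p in each direction, and none of them passed edgeR's adjusted test. In the authors' deposited table the smallest p belonged to Mertk, a receptor tyrosine kinase with which macrophages take up dying cells, at a log2 fold change of -1.65 for model over DMDD liposome (3.14-fold higher in DMDD liposome, adjusted p = 1.55e-06). Mertk measured 6.08 ± 1.07 CPM in the model group and 19.1 ± 3.43 CPM in the DMDD liposome group (SD, n = 3 each). Pdk4, a kinase that restrains pyruvate dehydrogenase, was next in the authors' deposited table, at 10.7-fold higher in DMDD liposome (adjusted p = 5.71e-06), with 0.651 ± 0.189 CPM against 7.04 ± 4.08 CPM. Lbp, which binds bacterial lipopolysaccharide, measured 5.34 ± 1.82 CPM in model and 18.4 ± 5.49 CPM in DMDD liposome. The chemokines Ccl6 and Ccl9 were 2.88-fold and 2.06-fold higher in DMDD liposome in the authors' deposited table, and the NAD-consuming surface enzyme Cd38 was 2.63-fold higher. Gda, the guanine deaminase, stood at 2.19-fold, and the extracellular proteins Ccdc80 and Itih5 at 2.48-fold and 6.26-fold, in the authors' deposited table. Piwil4, of the Piwi family of small-RNA binding proteins, was 2.22-fold higher there by the authors' deposited table.

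Of the genes lower in DMDD liposome in the authors' deposited table, Fgfbp1, a carrier of fibroblast growth factors, had the smallest p, at 3.72-fold higher in model (adjusted p = 3.11e-05). Fgfbp1 measured 86.9 ± 38.9 CPM in model and 23.5 ± 1.99 CPM in DMDD liposome (SD, n = 3 each). The serine protease gene Tmprss4 had 100, 198 and 194 counts in the model libraries and 25, 13 and 49 in the DMDD liposome libraries, and Eln, which encodes elastin, measured 55.4 ± 23.1 CPM against 16.3 ± 4.42 CPM. In the authors' deposited table Itga6, an integrin subunit of epithelial adhesion to the basement membrane, was 1.42-fold higher in model, and the nonmuscle myosin gene Myh14 1.68-fold higher. Odaph, Rab6b and Ankrd22 were 2.61-fold, 2.13-fold and 4.89-fold higher in model in the authors' deposited table. Mcpt4, a mast cell protease gene, had 18, 263 and 230 counts in the model libraries and 7, 6 and 21 in the DMDD liposome libraries, so that its groups overlapped. All 58 calls of the authors' deposited table were shared by the DESeq2 fit, in the same direction, but that fit repeats the authors' test on the same counts. Of the 58, edgeR tested 54, and all 54 had an unadjusted p under 0.05. The other 4, Dsg3, Ehf, Krt16 and Mmp1a, were left out by the filter on low counts. The groups' 3 values did not overlap for 55 of the 58 genes, and for 18 of the 58 model replicate 1 lay nearer the DMDD liposome mean than the mean of the other model libraries. The 58 were called with model replicate 1 in the model group, which favors genes where it resembles the other model libraries, so both counts were shaped by that selection. Among the 835 genes that separated the groups without it (edgeR unadjusted p under 0.01), it lay nearer the DMDD liposome group for 88.1%. Those genes were picked for a gap between the other libraries, which can itself draw a left-out library towards the opposite group. In the same count for each other library, 12.5% to 64.2% of genes lay nearer its opposite group.

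**Figure D1:**
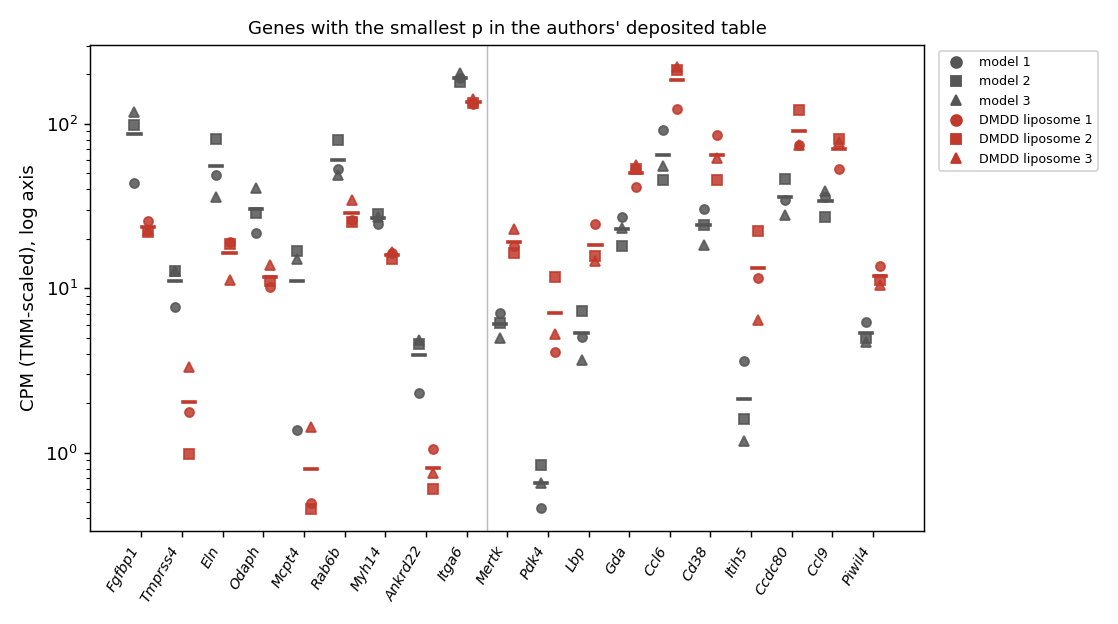
Each column shows the TMM-scaled CPM, on a log axis, of a gene named here from the 10 smallest p-values per direction in the authors' deposited table, with points for the 3 model libraries (gray) and the 3 DMDD liposome libraries (red) and bars for the group means. Fgfbp1 averages 86.9 CPM in model and 23.5 CPM in DMDD liposome, Mertk 6.08 and 19.1 CPM, and the points of the groups overlap for Mcpt4.

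Every tested gene of the cholesterol synthesis list had a negative log2 fold change, and camera placed the list lower than other genes (adjusted p = 6.71e-11 with the preset correlation, adjusted p = 0.875 with an estimated correlation). Lss, which closes the sterol rings from oxidosqualene, measured 47.3 ± 19.6 CPM in model and 26.2 ± 2.25 CPM in DMDD liposome (SD, n = 3 each), a log2 fold change of -0.85 ± 0.28 (SE) that went to -0.51 without model replicate 3. Dhcr7, which catalyses the last step to cholesterol, stood at -0.62 ± 0.16 (58.0 ± 11.3 CPM against 37.8 ± 3.74 CPM). Adjusted over the list alone, 16 of the 20 members passed edgeR's threshold, all lower, while over all genes tested 0 passed and the authors' deposited table called 0. The list's mean per library, centred on the 6 libraries, was -0.32 in model replicate 1 against 0.51 and 0.95 in model replicates 2 and 3, and lay between -0.48 and -0.28 in the DMDD liposome libraries. Model replicate 1 was thus inside the range of the DMDD liposome libraries. At the preset correlation the call held without any 1 library, and the mean log2 fold change of -0.85 moved to -0.55 without model replicate 3.

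Epithelial tumor cell markers fell as a list, with 12 of 14 members negative (camera adjusted p = 8.93e-05, adjusted p = 0.875 with an estimated correlation). Cldn7, a tight junction claudin, measured 97.4 ± 39.6 CPM in model and 41.2 ± 7.95 CPM in DMDD liposome, a log2 fold change of -1.24 ± 0.31, and was the 1 member called by the authors' deposited table. Esrp1, an epithelial splicing regulator, stood at -0.54 ± 0.16 and Krt14, a basal keratin, at -1.69 ± 0.50. None of the 14 members passed when adjusted over the list alone. Krt14 had 1057 counts in model replicate 1 against 4988 and 5261 in model replicates 2 and 3, and 831 to 1383 in the DMDD liposome libraries. Model replicate 2 also carried keratinocyte genes of the epidermis: the 12 measured genes of the skin list summed to 104 CPM there and to between 5.21 and 7.10 CPM in each of the other libraries. Krt1, a keratin of the upper epidermis, had 591 counts in model replicate 2 and 0 in the others, and Krt5, a basal keratin of the epithelial list that the count filter left out, had 1919 counts there and at most 2 elsewhere. Without model replicate 2 the epithelial list was still called (adjusted p = 0.00591). Its mean log2 fold change of -0.59 moved to -1.11 without model replicate 1 and to -1.16 without DMDD liposome replicate 3, fits in which the filter can admit other members.

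Mast cell and basophil markers fell, with 8 of 9 members negative (camera adjusted p = 0.000224, adjusted p = 0.875 with an estimated correlation). Mcpt4 had a log2 fold change of -3.79 ± 0.93, from 11.1 ± 8.50 CPM in model to 0.793 ± 0.552 CPM in DMDD liposome. Cma1, the mast cell chymase, stood at -2.69 ± 0.80, with 26, 149 and 121 counts in the model libraries and 8, 4 and 31 in the DMDD liposome libraries. Hdc, the enzyme that makes histamine, stood at -1.90 ± 0.55 (19.2 ± 12.1 CPM against 5.16 ± 2.91 CPM). The exception was Kit, a receptor also found on other cells, at 0.59. Of the 9 members, 5 passed when adjusted over the list alone, all lower, and the authors' deposited table called 1, Mcpt4. Per library the list's centred mean was -0.26 in model replicate 1, 1.40 and 1.53 in model replicates 2 and 3, and -1.51, -0.90 and -0.27 in the DMDD liposome libraries.

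Macrophage and monocyte markers rose, with 15 of 18 members positive (camera adjusted p = 0.000159, adjusted p = 0.875 with an estimated correlation). Lyz2, the lysozyme of myeloid cells, measured 664 ± 343 CPM in model and 1317 ± 361 CPM in DMDD liposome, a log2 fold change of 0.99 ± 0.39 (0.65 without model replicate 3). Arg1, which breaks down arginine, stood at 1.52 ± 0.64 (163 ± 110 CPM against 467 ± 216 CPM), and the lysosomal protease gene Ctsd at 0.45 ± 0.15. Among the 3 negative members, Cd163 stood at -0.54 and Mrc1 at -0.24. The count was 0 of 18 when adjusted over the list alone, and the authors' deposited table called 0. All 3 DMDD liposome libraries lay above all 3 model libraries in the list's centred mean, at 0.23 to 0.26 against -0.43 to -0.08. A separation in either direction has a chance of 10% for any list. The uncalled pericyte and smooth muscle list was also higher in all 3 DMDD liposome libraries, by a gap of 0.03 against 0.31 here. At the preset correlation the call held without any 1 library.

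Endothelial markers rose, with 11 of 14 members positive and a median log2 fold change of 0.38 (camera adjusted p = 0.0196, adjusted p = 0.875 with an estimated correlation). Egfl7, a factor secreted by vessel lining cells, stood at 0.76 ± 0.26, Emcn, a sialomucin of capillaries and veins, at 0.71 ± 0.26, and Esam, an adhesion molecule of endothelial junctions, at 0.73 ± 0.29 (0.43 without DMDD liposome replicate 2). Vwf, which encodes von Willebrand factor, was at -0.75. The call ended without model replicate 2 (adjusted p = 0.224), model replicate 3 (adjusted p = 0.0710) or DMDD liposome replicate 2 (adjusted p = 0.163), and the mean log2 fold change of 0.30 went to 0.16, 0.19 and 0.12 in those fits and to 0.57 without model replicate 1. Adjusted over the list alone, 0 of 14 passed. DMDD liposome replicate 2, the highest library for this list at a centred mean of 0.47, was also the highest for fat cell markers. Model replicate 1 came next at 0.30, above DMDD liposome replicates 1 and 3 (-0.01 and 0.02) and apart from model replicates 2 and 3 (-0.42 and -0.36).

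Immune checkpoint genes rose as a list, with 9 of 11 members positive and a median of 0.38 (camera adjusted p = 0.0256, adjusted p = 0.875 with an estimated correlation). The costimulatory ligands Cd80 and Cd86 stood at 1.04 ± 0.27 (3.29 ± 0.790 CPM against 6.75 ± 0.596 CPM) and 0.51 ± 0.18, and Pdcd1, which encodes the receptor PD-1, at 1.14 ± 0.46. Cd274, which encodes its ligand PD-L1, was at 0.05. The authors' deposited table called 0 members, and adjusted over the list alone 0 of 11 passed. The call ended without model replicate 1 (adjusted p = 0.0567), model replicate 2 (adjusted p = 0.194), DMDD liposome replicate 1 (adjusted p = 0.117) or DMDD liposome replicate 3 (adjusted p = 0.213), and the mean log2 fold change of 0.38 went to 0.39, 0.23, 0.30 and 0.16 in those fits and to 0.57 without model replicate 3. The list's centred means were 0.32, -0.28 and 0.46 in DMDD liposome replicates 1 to 3, beside 0.96, -1.02 and 0.69 for T cell markers, which were not called, and Pdcd1 had 187, 48 and 165 counts there. DMDD liposome replicates 1 and 3 were also the libraries highest for skeletal muscle markers, at centred means of 1.62 and 2.17.

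Hypoxia targets fell, with 15 of 16 members negative and a median of -0.36 (camera adjusted p = 0.000224, adjusted p = 0.875 with an estimated correlation). Car9, a carbonic anhydrase induced by low oxygen, measured 185 ± 26.7 CPM in model and 114 ± 13.8 CPM in DMDD liposome, a log2 fold change of -0.69 ± 0.14. Car9 was the 1 member to pass when adjusted over the list alone (adjusted p = 0.0226) and the 1 member called by the authors' deposited table. The glucose transporter gene Slc2a1 stood at -0.55 ± 0.25 (-0.32 without DMDD liposome replicate 1), and Ldha, which converts pyruvate to lactate, at -0.37 ± 0.16. The list's mean of -0.36 moved to -0.19 without DMDD liposome replicate 1 and to -0.21 without model replicate 3, and the call held in both fits. The groups overlapped, with centred means of 0.26, -0.19 and 0.48 in model replicates 1 to 3 and -0.60, 0.09 and -0.05 in DMDD liposome replicates 1 to 3. DMDD liposome replicate 1, the lowest, was also the lowest for immediate early genes (-0.95) and NF-kB genes (-0.63). Glycolysis enzymes, which share Ldha, Pgk1 and Slc2a1 with that list, also fell, with 13 of 16 negative and a median of -0.21 (camera adjusted p = 0.00127, adjusted p = 0.875 with an estimated correlation). Pfkl, a subunit of phosphofructokinase, stood at -0.35 ± 0.14 and Tpi1, the triosephosphate isomerase, at -0.32 ± 0.13. Of the 16 glycolysis genes, 0 passed when adjusted over the list alone. Gapdh, another member, had only 104 to 313 counts per library against 13409 to 26222 for Aldoa, so its level is uncertain. The glycolysis call ended without model replicate 1 (adjusted p = 0.0912) or DMDD liposome replicate 1 (adjusted p = 0.0603), and its mean of -0.18 went to -0.14 and -0.07 in those fits and to -0.30 without DMDD liposome replicate 2.

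All 22 DNA replication and S phase genes had negative log2 fold changes, with a median of -0.18, and the list was called lower (camera adjusted p = 0.0256, adjusted p = 0.875 with an estimated correlation). Rfc3, a subunit of the clamp loader, stood at -0.38 ± 0.18, Pola1, the catalytic subunit of DNA polymerase alpha, at -0.46 ± 0.23, and Cdt1, a replication licensing factor, at -0.41 ± 0.23. Without model replicate 2 Pola1 went to -0.27 and Cdt1 to -0.27, and without model replicate 1 Cdt1 went to -0.65. When adjusted over the list alone, 0 of 22 passed. The list's centred mean was -0.45 in model replicate 1 and 0.38 and 0.31 in model replicates 2 and 3, with the DMDD liposome libraries in between at -0.15 to -0.02. The call ended without model replicate 2 (adjusted p = 0.675), model replicate 3 (adjusted p = 0.341) or DMDD liposome replicate 3 (adjusted p = 0.112). The mean log2 fold change of -0.21 went to -0.08, -0.12 and -0.18 in those fits and to -0.43 without model replicate 1.

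Skeletal muscle markers rose as a list (median log2 fold change 1.97, 12 of 14 positive, camera adjusted p = 0.0256, adjusted p = 0.875 with an estimated correlation). The muscle creatine kinase gene Ckm had 210, 4 and 767 counts in the DMDD liposome libraries and 10, 9 and 4 in the model libraries. Myl1, a muscle myosin light chain, and Atp2a1, the calcium pump of fast muscle, likewise had more counts in DMDD liposome replicates 1 and 3 (113 and 138, and 226 and 351) than in replicate 2 (3 and 11). In the model libraries Myl1 had 19, 5 and 2 counts and Atp2a1 56, 13 and 5. The call ended without DMDD liposome replicate 1 (adjusted p = 0.191) or replicate 3 (adjusted p = 0.501), and the mean log2 fold change of 1.92 went to 1.77 and 1.28 in those fits. Fat cell markers rose as a list (median 1.22, all 9 positive, camera adjusted p = 0.0256, adjusted p = 0.875 with an estimated correlation). Car3, a carbonic anhydrase abundant in fat and muscle, had 79, 443 and 14 counts in the DMDD liposome libraries and 0, 6 and 0 in the model libraries. Cfd, the fat cell product adipsin, had 120, 146 and 3 counts against 7, 21 and 6, and Plin4, a lipid droplet coat protein gene, 15, 249 and 11 against 0, 21 and 12. Without DMDD liposome replicate 2 the mean of 1.98 dropped to 0.76 and the call ended (adjusted p = 0.301). The call also ended without model replicate 1 (adjusted p = 0.144), where the mean stayed at 1.96. Adjusted over the list alone, 1 fat gene (Car3) and 0 muscle genes passed.

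**Figure D2:**
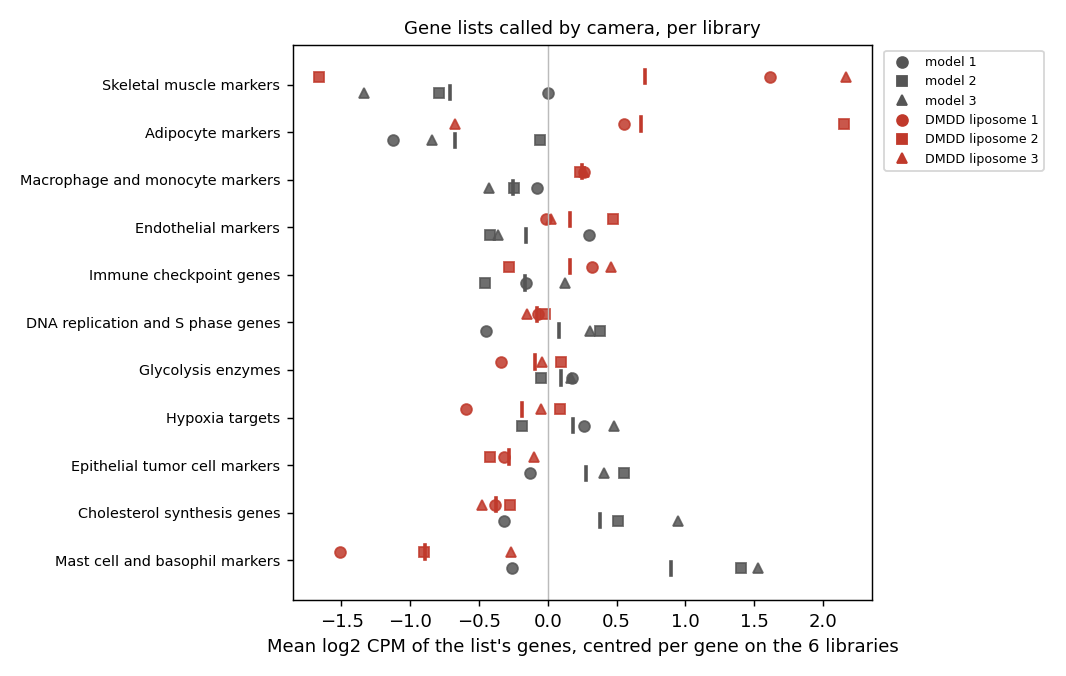
Each row is a gene list called by camera, and the horizontal axis is the mean log2 CPM of its genes after centring each gene on the 6 libraries. Points are libraries (gray, model; red, DMDD liposome) and vertical bars are group means; for cholesterol synthesis, model replicate 1 sits at -0.32 among the DMDD liposome libraries while model replicates 2 and 3 sit at 0.51 and 0.95.

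Of the 29 lists not called, cytotoxic lymphocyte markers came nearest the threshold, with 12 of 13 members positive and a median of 0.66 (camera adjusted p = 0.0522). NRF2 antioxidant targets had a median of 0.18 (adjusted p = 0.0617), fatty acid synthesis genes -0.17 (0.0734), NF-kB and inflammatory cytokine genes -0.20 (0.0780), mitotic and G2/M genes -0.33 (0.0889) and interferon gamma and antigen presentation genes -0.09 (0.0903), the p-values in parentheses being camera's adjusted p. Stress and death programs lay near 0: apoptosis genes had a median of 0.04 over 20 members (adjusted p = 0.884), p53 targets 0.10 over 15 (0.329), the unfolded protein response 0.03 over 17 (0.749), autophagy and lysosome genes -0.04 over 17 (0.617), and ferroptosis and iron handling genes 0.13 over 14 (0.929). T cell markers had a median of 0.64 (adjusted p = 0.168), B cell and plasma cell markers 0.41 (0.538), dendritic cell markers 0.12 (0.573), neutrophil markers 0.01 (0.363) and type I interferon response genes 0.19 (0.404). Stromal lists gave 0.26 for fibroblast and collagen genes (0.935), 0.28 for pericytes and smooth muscle (0.171), 0.18 for angiogenic factors (0.404), -0.08 for matrix metalloproteinases (0.292), 0.19 for epithelial to mesenchymal transition (0.884) and -0.08 for nerve and Schwann cells (0.824). Housekeeping and growth lists gave -0.07 for cytosolic ribosomal proteins (0.168), -0.07 for mitochondrially encoded genes (0.348), -0.03 for nuclear oxidative phosphorylation (0.538), -0.24 for histones (0.668), 0.09 for heat shock genes (0.184), -0.04 for immediate early genes (0.245) and 0.00 for PI3K, AKT and mTOR genes (0.749). In 6 of these lists the median, the mean and camera's direction differed in sign: the unfolded protein response (mean -0.03, direction higher), immediate early genes (mean 0.04, lower), neutrophil markers (mean -0.11, lower), epithelial to mesenchymal transition genes (mean -0.02, higher), nerve and Schwann cell markers (mean 0.10, lower) and PI3K, AKT and mTOR genes (mean 0.02, lower). Adjusted over the list alone, 3 neutrophil genes passed and 0 in each of the other uncalled lists. These were Prtn3, a granule protease gene (log2 fold change 2.19 ± 0.53, 0.549 ± 0.325 CPM in model against 2.54 ± 0.646 CPM in DMDD liposome), S100a9, a calcium-binding alarmin gene (-0.93), and Hdc, which the mast cell list also holds. S100a9 was lower in DMDD liposome in the authors' deposited table as well, at 1.92-fold higher in model.

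The libraries did not fall into their groups on the largest component of variation. Component 1 of log2 CPM took 38.9% of the variance and set model replicates 2 and 3 (32.1 and 40.9) apart from model replicate 1 (-14.0) and the 3 DMDD liposome libraries (-28.6 to -11.4). Component 2 took 24.7% and set DMDD liposome replicate 2 (42.7) apart from the rest. Across the 12891 tested genes, which are not independent replicates, model replicate 1 had a mean Pearson correlation of 0.977 with the DMDD liposome libraries and 0.966 with the other model libraries. Mitochondrially encoded genes took 1.82% to 4.00% of counts, with the highest shares in model replicate 3 (4.00%) and DMDD liposome replicate 2 (3.51%). Counts were very uneven among these genes, at 112559 to 295978 per library for mt-Co1 and 28 to 77 for mt-Co2, so the shares may be undercounts. The labels name no batch, day or litter, so no within-batch value could be given.

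**Figure D3:**
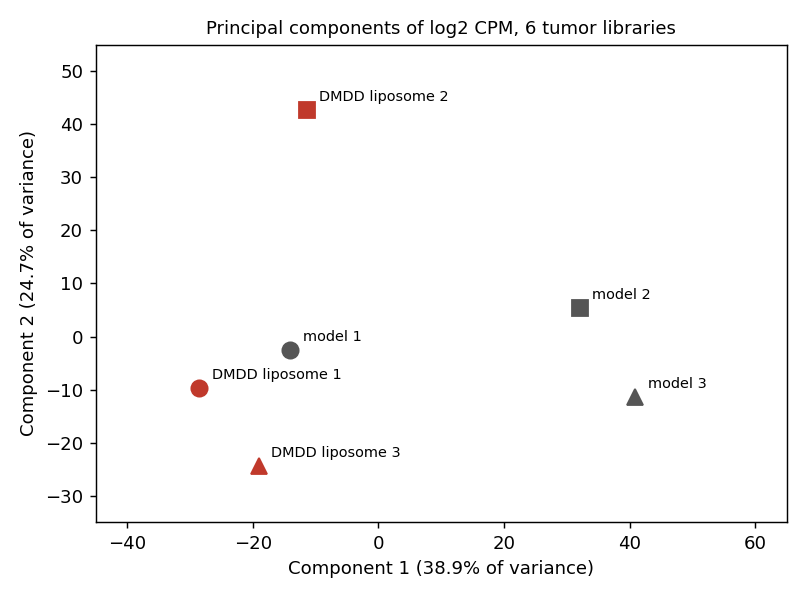
The axes are the first principal components of log2 CPM over 12891 genes, in component units with the percent of variance on each, and each point is a library (gray, model; red, DMDD liposome). Model replicate 1 (-14.0 on component 1) sits with the DMDD liposome libraries and away from model replicates 2 and 3 (32.1 and 40.9).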

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

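DESeq2 without each library and edgeR with a robust prior were chosen after seeing the data; the other alternatives were fixed before. The count of 0 genes from edgeR (986 at an unadjusted p under 0.05) was also 0 with DESeq2 size factors, no filter, voom with quality weights and a robust prior. A threshold of 0.01 on the same fit had to give 0 as well. DESeq2's Wald test, which repeats the authors' test on the same counts, called 59 genes, 31 higher and 28 lower, and shared 58 with the authors' deposited table. The edgeR test shared 0 with that table. The cause was not tested, though on simulated counts of the filtered genes DESeq2 made more false calls. Leaving out a library gave edgeR 0 to 112 genes (0 to 43 higher, 0 to 69 lower), the 112 without model replicate 1 and 0 in each of the other 5 fits. DESeq2 then gave 18 to 867 genes (9 to 438 higher, 9 to 429 lower): 867 without model replicate 1, 30 and 18 without model replicates 2 and 3, and 20, 128 and 87 without DMDD liposome replicates 1 to 3. Of the authors' 58 calls, these fits shared 57, 19, 13, 13, 31 and 30 in that order.

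The 11 list calls became 0 with an estimated correlation and 0 with fry, which asks whether a list's genes move, on balance, one way. Without a library there were 9 to 19 calls, the 19 without DMDD liposome replicate 2, and 8 or 9 of the 11 were shared each time. DESeq2 size factors gave 12, all 11 shared. For 5 lists (cholesterol synthesis, epithelial, macrophage, mast cell and hypoxia) the call held in all 6 left-out fits. Those fits kept the preset correlation and shared most of their libraries. The held calls are therefore no separate evidence, and none of them held with an estimated correlation. All 384 alternative values of the 32 list genes under the naming rule kept their sign, as did all 240 of the 20 genes with the smallest p in the authors' deposited table. Of these, 8 of the 20 and 4 of the 32 passed edgeR's adjusted threshold without model replicate 1. The genes had been picked for a small p in the same libraries that the alternatives reuse. Their kept signs were thus nearly fixed in advance and are no separate evidence.

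The numbers were not taken to pair the samples: deviations of same-numbered libraries correlated at 0.0876, 0.114 and 0.121 across genes, not all over 0.1, although each library correlated best with its own number. With a replicate block edgeR called 0 genes, and camera called 15 lists, the 11 included. Another scaling moved the median log2 fold change of all genes by -0.01.

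Depth limits genes near 3 counts, such as some of the muscle and fat genes in the model libraries.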

Other observations

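Of the tests in this part, those of splits of the samples were planned, and those on model replicate 1, on cholesterol genes and on muscle and fat genes were chosen only after the result was seen.

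Lymphocyte and interferon genes varied more within the DMDD liposome group than between the groups. The centred mean of the T cell list was 0.96 and 0.69 in DMDD liposome replicates 1 and 3 and -1.02 in replicate 2, against -0.41 to -0.01 in the model libraries. Cd8a, the coreceptor of cytotoxic T cells, had 460, 66 and 366 counts in the DMDD liposome libraries and 121, 87 and 169 in the model libraries. Interferon gamma and antigen presentation genes stood at -0.85 in DMDD liposome replicate 2 and 0.57 in replicate 3. Fibroblast and collagen genes went the other way, at 0.81 in DMDD liposome replicate 2 against -0.37 and -0.44 in replicates 1 and 3, with 55729 counts of Col1a1 there and 21790 and 23010 in the others. Immediate early genes, which respond within minutes to stimulation, spanned -0.95 in DMDD liposome replicate 1 to 0.95 in replicate 2, and Fos had 292 and 4587 counts there. Cd8a, Col1a1 and Fos were chosen after their values were seen.

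Among lists too small to test, the hemoglobin gene Hbb-bs had 64 to 303 counts in every library, and the platelet factor gene Pf4 had 1137 counts in DMDD liposome replicate 2 and 173 to 455 elsewhere. Of luminal genes, Csn3, a milk casein gene, had 44 counts in DMDD liposome replicate 1 and at most 9 elsewhere, and Gata3 had 2959 in model replicate 3 and 1125 to 1574 elsewhere.

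The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. By edgeR the real split gave 0 genes and the highest other split 0; since no count can fall below 0, all 10 splits had to give as many, and this says nothing about chance. At an unadjusted p under 0.05 the real split gave 986 genes. Grouping model replicate 1 with DMDD liposome replicates 1 and 2 gave 1064, and grouping it with DMDD liposome replicates 1 and 3 gave 1558. The remaining splits gave 133 to 757. For lists called by camera the real split gave 11 and the highest other 18, and 6 of the 10 splits gave as many. With DESeq2 the real split gave 59 genes and the highest other 259, and 3 of the 10 gave as many. The split with 259 set model replicate 1 and DMDD liposome replicates 1 and 3 against the rest, and points to a structure of the samples other than their groups.

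Model replicate 1 lay with the DMDD liposome libraries in component 1 and in correlation. Sequencing depth is argued against as the whole cause: the library correlated better with DMDD liposome than with the other model libraries by 0.0112 as deposited, and by at least 0.0101 in 100 draws that thinned DMDD liposome libraries to 6518750 counts and model libraries to 13037500, turning the depth order round. A wrong label on this library remains open: over the 835 genes that separated the groups without it (edgeR unadjusted p under 0.01), its median position was 0.943 on a scale from the other model libraries at 0 to DMDD liposome at 1. The genes were picked for a gap between the other libraries, which can itself move a left-out library off 0. For each other library the median position towards its opposite group was between 0.0187 and 0.681. A swap cannot be told apart from other causes, because the highest median position of a DMDD liposome library towards the model group was 0.681 (replicate 2), with replicate 3 also past the middle at 0.572, so that a high position is not special to a swapped library, and the mean correlation of replicate 2 with model replicates 2 and 3 minus that with its own group was -0.00547. Variation between tumors of the model group also stays open, untested, and the list of mitotic and G2/M genes stood at -0.83 in this library, below both the other model libraries (0.54 and 0.60) and the DMDD liposome libraries (0.01, -0.17 and -0.15), so that on this list it lay with neither group.

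The fall of cholesterol synthesis genes rests on model replicates 2 and 3 (centred means 0.51 and 0.95). Model replicate 1 (-0.32) lay within the DMDD liposome range of -0.48 to -0.28. Component 1 set the same model replicates 2 and 3 apart. A treatment effect therefore cannot be told apart from that structure of the samples. A trend with expression level or gene length is argued against: among 10000 random lists matched on both, the lowest median log2 fold change was -0.225, against -0.86 for the list. A lower share of epithelial tumor cells stays open and cannot be told apart from a change within cells. The list's group difference minus that of the epithelial list was -0.20 (-0.201 ± 0.268, SE; exact permutation p = 0.5, where the smallest possible is 0.1), too wide to decide.

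Muscle and fat transcripts in DMDD liposome libraries may come from tissue next to the tumor that was carried into some samples. For muscle, 2 of the 3 DMDD liposome libraries lay over 1 log2 unit above every model library, with 78.6% of the members higher in both than in every model library, while the lowest DMDD liposome library lay -1.67 (log2) from the highest model library. For fat, 1 library did so, with 88.9% of the members, and the lowest lay at -0.62 (-0.618). These values describe the pattern and test nothing further, since the criterion was set after they were seen and the libraries were picked for being high, so carry-over cannot be told apart from a treatment effect present in only some tumors. Acta1, the most counted muscle gene named here, had 633 and 1425 counts in DMDD liposome replicates 1 and 3 and 11 in replicate 2. It had 164, 25 and 9 counts in model replicates 1 to 3.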
